A study of Mus musculus with 12 samples.

How the data were processed

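RNA was measured by sequencing in adipose vascular anomalies and in normal adipose tissue of C57BL/6 mice. Per the labels, the anomalies came from mice that carried a VEC-Cre transgene, a Cre recombinase driven by the promoter of the VE-cadherin gene Cdh5. The same mice carried a Sleeping Beauty transposase, an enzyme that moves transposons within the genome, and an onc3 transposon. The control mice lacked Cre. Per the labels' protocols, tissue was snap-frozen, RNA was extracted with a lipid tissue kit, and poly-A libraries were made with an unstranded kit.

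The submitters' processing notes name STAR as the aligner, limma, and the mouse builds mm10 and GRCm38, without versions. The authors deposited 1 table of 32774 Ensembl gene identifiers by 12 libraries. Its values are on the log2 scale, as normalized log2 CPM with a small prior, and the lowest value, -6.97, was shared by the libraries. The normalization function and the prior count were not given in the sources used here. After the prior was subtracted, the linear values of each library were whole multiples of 1 step. 100% of the values lay within 0.1 of a whole number. These multiples were read as recovered reads, and their totals give the depth. The size of each step implied a composition factor between 0.795 and 1.41 per library, so the deposited values had been scaled for composition and not only for the library total.

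Library totals ran from 10337258 to 33980694 recovered reads, except in the library of anomaly animal M580. There the steps summed to 953994 and 1 step was worth 0.742 CPM, which limits the precision of low genes in that library. Genes at exactly 1 step there had a median of 0.126 CPM in the other anomaly libraries, so low values of M580 may also be too high. In the other 11 libraries 3 reads were worth between 0.0914 and 0.267 CPM. The reads carry no molecular identifiers, so depth speaks of counting error alone.

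Animals were taken from the titles. The 8 anomaly libraries came from 7 animals, since a leg and an arm piece both belong to animal M566, and these were averaged on the log2 scale. The design text of the series counts 8 anomaly animals, and the 7 used here follow the titles. With the pieces as separate replicates 4779 genes passed. Each of the 4 control libraries came from its own animal. The first header line of the table gives the column of anomaly animal M605 a control name, while the second header line and the labels make it an anomaly. It was kept as an anomaly. Across genes, its median Spearman correlation was 0.904 with the other anomaly libraries and 0.804 with the controls, and genes are not independent replicates. Gene names came from the reference table, which matched 32671 identifiers. The table itself pairs 14864 identifiers with a symbol, and 14521 of the 14858 symbols present in both were equal. Coordinates are those of GENCODE vM21, on GRCm38.

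The test planned before the data were examined was a count model. Because the deposited values are log2 values, limma (version 3.58.1, with statmod 1.5.0 in R 4.3.3) was used in its place, as the plan allowed. Genes with a mean of at least 1 log2 CPM over the 11 animals were tested. Since 7 of these are anomaly animals, a gene scarce in the controls can pass this filter through its anomaly values. The linear model was followed by empirical Bayes moderation with a mean trend and robust variances, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p printed for a gene comes from this limma test unless another tool is named. A log2 fold change is the anomaly mean minus the control mean. It rests on values that include the authors' prior, so the change of genes near the floor depends on that prior. A gene with 0 reads stands at the floor of -6.97 log2 CPM, below the value of 1 read, and can pull a mean far down. The SE is that of the moderated test.

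Also fixed before the data were examined were 35 gene lists: markers of endothelium (general, arterial and Notch, venous and activated, lymphatic, sprouting), pericytes and smooth muscle, adipocytes (mature, brown and beige), fibroblasts, skeletal muscle, skin, glands, mesothelium and nerve, of macrophages, neutrophils, T and NK cells, B and plasma cells, mast cells, erythroid cells, platelets and lymph node stroma, and genes of lipogenesis, the respiratory chain, matrix, coagulation, heme and iron, hypoxia, cell cycle, cytokines, interferon response, vascular anomaly disease, depot position, immediate early response and sex. Of these, 33 were tested with limma's camera, which asks whether a list moves differently from the other genes, with a preset correlation of 0.01 between genes and at least 3 measured members. The sex-linked list was read per library and the mesothelium list had 2 measured members. The filter on low values left 4 of 10 lymph node stroma, 5 of 12 platelet, 6 of 15 neutrophil and 7 of 12 erythroid members. Members scarce in the controls can pass it through their anomaly values, so those left may lean toward rises. Beside camera stand camera with a correlation estimated from the data and fry, which asks whether the genes of a list move, on balance, one way. The p-values of the lists were adjusted over the lists. The count of a list's members past the threshold is given over all genes tested and adjusted over the list alone.

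Named genes followed a rule. The first part took genes past the threshold with a symbol that was not a predicted model, a mean of at least 10 CPM in the higher group, and no overlap between the animals of the groups. Of these it named the 6 with the largest rise and the 6 with the largest fall. The second part took, for each list that passed camera or had at least 3 members past the threshold, the 2 members with the smallest p. The third took Cdh5, and the fourth Xist and Ddx3y per library.

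Anomalies whose titles say subQ were compared with those whose titles say fat in a limma fit of 3 groups, with the controls in the fit for the spread. The pieces of M566 were compared by the Pearson correlation, across genes, of their deviations from the anomaly mean. Gaps between list scores were tested by exact permutation of the 11 animals, two-sided. The limma and camera steps were tested on simulated data. With 200 of 12955 genes changed in a simulated anomaly against control comparison, limma called 78% of the genes lowered by 2 on the log2 scale and 42% of those lowered by 1. It called 36% of the genes raised by 1 and 72% of those raised by 2, with 3 false calls among 117. Camera called the changed list and 0 of 30 unchanged lists. The simulated genes varied independently, so this cannot show how the preset correlation behaves where genes move together. The limma simulation also gave M580 the lowest depth of the other animals and changed far fewer genes than passed in the real data.

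The alternatives tried were median-ratio, upper quartile and library-total scaling, other filters on low values, pseudocounts of 0.1, 0.5 and 1, limma-voom on recovered reads, other ways of using M566, an identifier-letter covariate, other sample selections, each animal left out, and other thresholds. How the authors' counting treated reads of near-identical copies, such as the globin, Oas and ribosomal protein genes, was not examined here, so their values are uncertain. Because the kit does not mark strand, antisense genes cannot be told from the genes they overlap and none is named. Sequencing reads were not analysed here.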

Results

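Whole-tissue transcriptomes were collected from adipose vascular anomalies, which are malformed vessel-rich lesions in fat, and from normal mouse adipose tissue. The anomalies came from mice that carried Cre under the promoter of the endothelial cadherin gene Cdh5 together with a Sleeping Beauty transposon system. There were 8 anomaly libraries from 7 animals and 4 control libraries from 4 animals. Animal M566 gave a leg and an arm piece, whose log2 values were averaged. Anomaly totals lay between 11749969 and 29763059 recovered reads in 7 libraries, and the steps of the library of animal M580 summed to 953994. Control totals lay between 10337258 and 33980694. The 10 most abundant genes held between 3.49% and 18.5% of a library's reads.

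The first comparison asked how the anomalies differ from normal adipose tissue. Genes of the fat cell were far lower in the anomalies, with 21 of 22 measured adipocyte genes past the test (median log2 fold change -4.40). Respiratory chain genes were lower by less (median -1.22), with 33 of 33 past the test as deposited and 23 with library totals. Genes of dividing cells were higher, with 23 of 23 cell cycle genes past the test, and so were 12 of 20 macrophage, 15 of 20 interferon response and 8 of 22 endothelial genes. The glucose transporter gene Slc2a4 fell from 8.60 ± 0.40 to 4.88 ± 0.75 log2 CPM (mean ± SD, n = 4 control and 7 anomaly animals). The proliferation marker Mki67 rose from 3.51 ± 0.37 to 6.46 ± 0.77 log2 CPM. Of 12955 genes tested, 1985 were higher and 3001 lower in the anomalies at an adjusted p under 0.05.

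Among genes whose animals did not overlap between the groups, Chga had the largest rise. Chga, which encodes chromogranin A of secretory granules (chromosome 12, 102554969 to 102565028), was 138-fold higher, with a log2 fold change of 7.11 ± 1.37 (SE) and an adjusted p of 0.00318. In control F539 it stood at -3.37 log2 CPM, against -1.04 to 0.89 in the other controls, and without F539 the change was 76.9-fold (log2 6.27, adjusted p = 0.00820). Spp1, the gene of the secreted matrix protein osteopontin (chromosome 5, 104435118 to 104441050), rose by 5.19 ± 0.99 (adjusted p = 0.00308). Ccn4, a secreted matricellular protein gene (chromosome 15, 66891320 to 66923201), rose by 5.08 ± 0.96. Mfap4, a microfibril-associated protein gene (chromosome 11, 61485431 to 61488900), rose by 4.96 ± 0.79. Cd5l, made by macrophages (chromosome 3, 87357881 to 87371073), rose by 4.83 ± 0.83, and the collagenase gene Mmp13 (chromosome 9, 7272514 to 7283331) by 4.75 ± 1.15. Mmp13 was past the threshold with limma (adjusted p = 0.00897) and not with limma-voom (adjusted p = 0.0835). The pieces of M566 lay far apart in Chga, at 1.46 log2 CPM in the leg and 9.03 in the arm. Spp1 stood at 7.08 in the leg and 2.24 in the arm. The arm value of Spp1 lay below the 3.49 of control F539, so its groups do not overlap only after the pieces are averaged. Leaving out 1 animal moved some of the folds above by more than 1.5 times. Without F539 Spp1 was at 5.79 and Ccn4 at 5.97, without M602 Spp1 was at 4.59 and Mfap4 at 4.36, without 18f Chga was at 7.92, and without M610 Mmp13 was at 3.98.

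The largest falls were in Tmem45b, a transmembrane protein gene (chromosome 9, 31426196 to 31464462), and in Alb, the serum albumin gene (chromosome 5, 90460897 to 90476602). Tmem45b had a log2 fold change of -6.39 ± 1.09 (SE, adjusted p = 0.00192) and Alb of -6.38 ± 0.86 (adjusted p = 0.00098). Aldh1a7, an aldehyde dehydrogenase gene (chromosome 19, 20692953 to 20727562), changed by -5.94 ± 1.20. Tmem179 (chromosome 12, 112500189 to 112516747) changed by -5.88 ± 1.06 and Vat1l (chromosome 8, 114205612 to 114374071) by -5.82 ± 0.67. Pck1, the gene of the gluconeogenic and glyceroneogenic enzyme PEPCK (chromosome 2, 173153048 to 173159273), changed by -5.80 ± 1.42 (adjusted p = 0.00946 with limma and 0.0968 with limma-voom). In M580, Alb, Aldh1a7, Tmem179 and Vat1l stood at exactly 1 step, -0.41 log2 CPM, and without M580 their log2 fold changes were -6.45, -5.70, -5.61 and -5.88. In the leg piece of M566 Vat1l stood at the floor, -6.97 log2 CPM, against 0.74 in the arm piece. Over 27 alternatives the change of Vat1l lay between -6.13 and -4.23. Without M610 the changes of Tmem45b, Aldh1a7, Tmem179 and Pck1 were -5.75, -5.06, -5.20 and -5.12, and that of Pck1 was -6.59 without 18f. In the fat-titled anomalies alone Pck1 changed by -2.46 and was not past the threshold (adjusted p = 0.109).

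**Figure D1:**
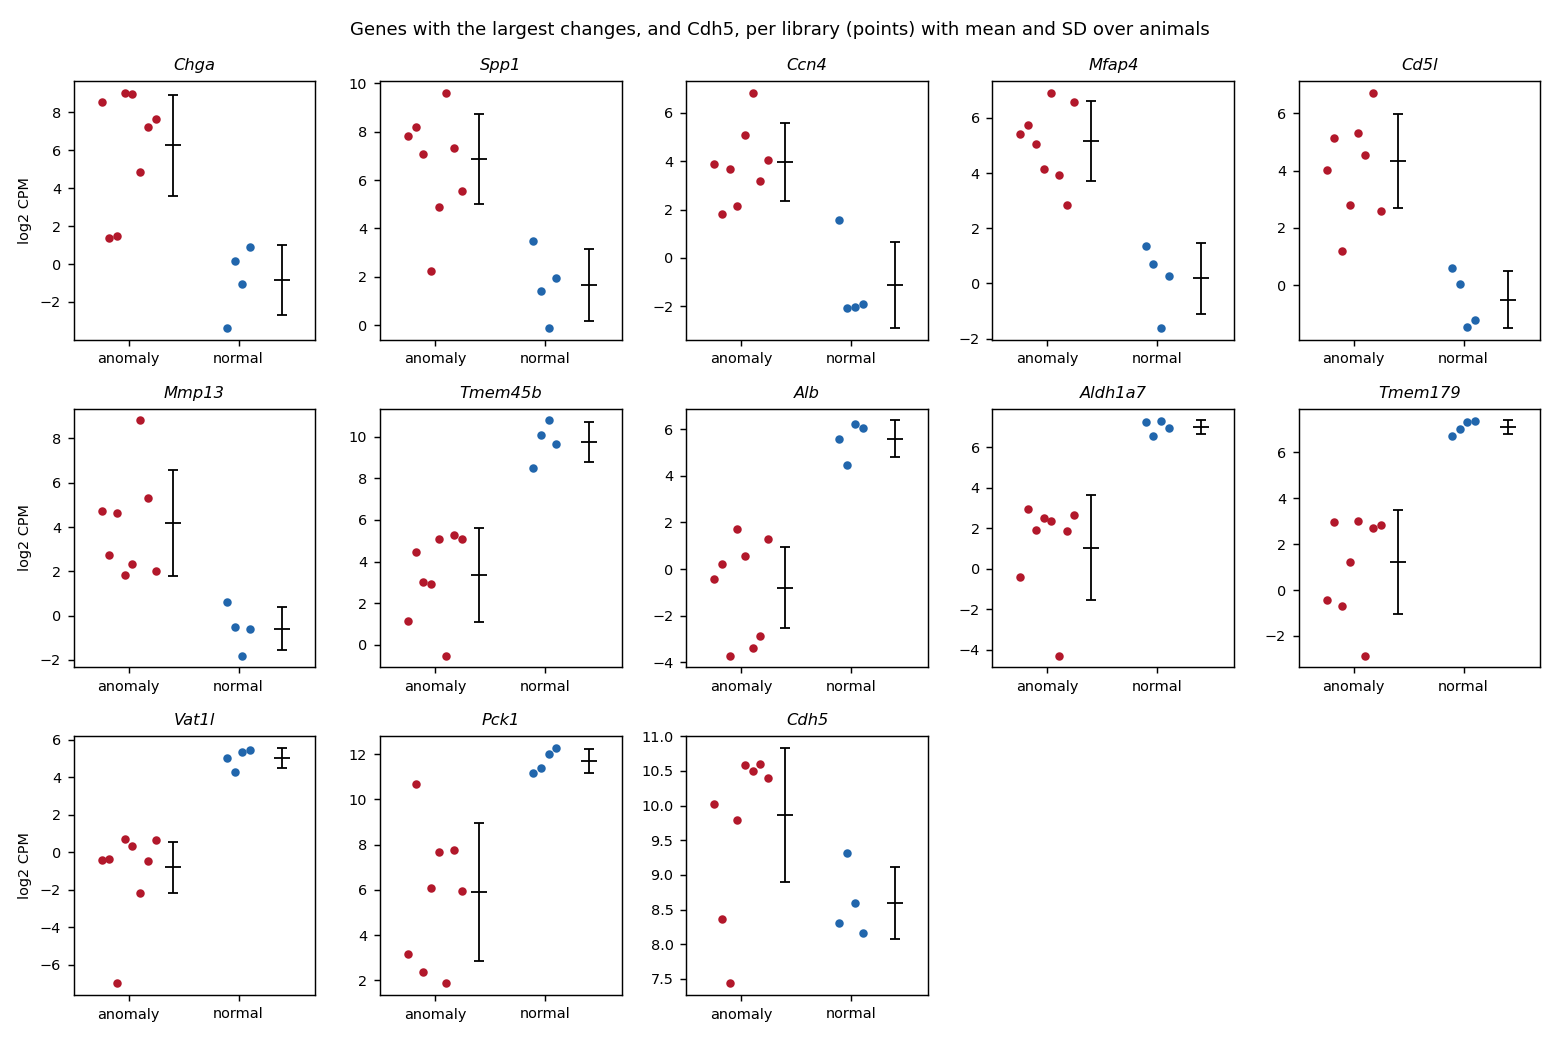
Log2 CPM (vertical axes) of the 12 genes with the largest changes and of Cdh5 in each anomaly and normal adipose library (points), with the mean and SD over animals (bars). The mean of Chga was 6.27 in the anomalies and -0.84 in normal adipose, and that of Alb was -0.80 and 5.58.

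Genes of adipocytes, of lipogenesis and of the respiratory chain were lower. In the mature adipocyte list 21 of 22 members fell, and 22 when adjusted over the list alone, with a median log2 fold change of -4.40 (camera adjusted p = 1.52e-07, adjusted p = 0.430 with an estimated correlation). Slc2a4 changed by -3.72 ± 0.38 and Agpat2, an enzyme gene of triglyceride synthesis, by -4.23 ± 0.52. In de novo lipogenesis 13 of 16 members fell, 13 also adjusted over the list alone, with a median of -3.12 (camera adjusted p = 2.32e-05, adjusted p = 0.430 with an estimated correlation). Dgat2, which makes triglycerides, changed by -5.01 ± 0.76, and Srebf1, a regulator of lipogenic genes, by -1.83 ± 0.29. In the brown and beige adipocyte list 6 of 8 members fell, and 8 adjusted over the list alone, with a median of -2.78 (camera adjusted p = 0.00286, adjusted p = 0.384 with an estimated correlation). Ppargc1a, a coactivator of mitochondrial genes, changed by -3.65 ± 0.58, and Ppara, a regulator of fatty acid oxidation, by -3.23 ± 0.64. Both stood at 1 step in M580, and without it their changes were -3.54 and -3.09. In the mitochondrial respiratory chain list 33 of 33 members fell, 33 also adjusted over the list alone, with a median of -1.22 (camera adjusted p = 4.77e-11, adjusted p = 0.430 with an estimated correlation). Sdha, a subunit of succinate dehydrogenase, changed by -1.95 ± 0.26 and Ndufs1, of complex I, by -1.42 ± 0.20. With scaling by library totals 23 respiratory chain and 20 mature adipocyte members were lower.

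Endothelial genes were higher as groups by camera, with 8 of 22 endothelial members past the threshold as deposited and 16 with library totals. Library totals moved the median of all genes by 0.43 and raised the count of genes higher from 1985 to 4618. In the endothelial list 8 of 22 members rose, 8 also adjusted over the list alone, with a median log2 fold change of 1.02 (camera adjusted p = 0.000408, adjusted p = 0.461 with an estimated correlation). Icam2, an adhesion molecule gene, rose by 1.84 ± 0.43, and Ecscr, an endothelial surface gene, by 1.81 ± 0.43. In the arterial and Notch list 2 of 16 rose, and 0 adjusted over the list alone (median 0.93, camera adjusted p = 0.00693, adjusted p = 0.461 with an estimated correlation). These were Notch4, a Notch receptor gene, at 1.56 ± 0.44, and Sox17, an arterial transcription factor gene, at 1.06 ± 0.38. In the venous and activated endothelium list 5 of 11 rose, 5 also adjusted over the list alone (median 1.35, camera adjusted p = 0.00293, adjusted p = 0.430 with an estimated correlation). With library totals 8 arterial and 7 venous members rose, but neither list passed camera (adjusted p = 0.111 and 0.0837). Flrt2 rose by 1.84 ± 0.40 and the leukocyte adhesion gene Vcam1 by 2.26 ± 0.52. The arterial list was not past the threshold with fry (adjusted p = 0.107) or in the fat-titled anomalies alone (median 0.22, camera adjusted p = 0.432), nor was the endothelial list with fry (adjusted p = 0.0850). Notch4 was not past the threshold without control M602 (adjusted p = 0.0505) or M2 (adjusted p = 0.0563). Sox17 was not past it without any one of F578, M610, M278, M605, F539, M602 or M2 (adjusted p from 0.0729 to 0.115).

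The lymphatic, sprouting and pericyte lists also passed camera, and the sprouting and pericyte lists each held 1 member that fell past the threshold. In the lymphatic endothelial list 4 of 10 members rose, 4 also adjusted over the list alone, with a median of 1.35 (camera adjusted p = 0.0216, adjusted p = 0.430 with an estimated correlation). Foxc2, a transcription factor gene of lymphatic valves, rose by 3.77 ± 0.79, and by 4.41 without F539 and 2.96 without M602. Itga9, an integrin gene, rose by 2.45 ± 0.46. In the fat-titled anomalies alone the lymphatic list was not past the threshold (median 1.27, camera adjusted p = 0.0705). Nor was it without M580 and M566 (median 1.41, camera adjusted p = 0.0541). In the angiogenic sprouting list 6 of 17 rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone (median 1.30, camera adjusted p = 0.00351, adjusted p = 0.461 with an estimated correlation). Angpt2, the gene of the vessel-destabilizing ligand angiopoietin 2, rose by 2.66 ± 0.53. Vegfa, the gene of the main endothelial growth factor, was the member that fell, with a log2 fold change of -2.19 ± 0.45. In the fat-titled anomalies alone neither gene was past the threshold, with Angpt2 at 1.67 (adjusted p = 0.0898) and Vegfa at -2.18 (0.0899). The sprouting list was not past it with fry (adjusted p = 0.0865) or in the fat-titled anomalies alone (median 0.61, camera adjusted p = 0.106). With library totals 12 sprouting members rose and 1 fell, and 4 lymphatic members rose, but neither list passed camera (adjusted p = 0.111 and 0.294). In the pericyte and smooth muscle list 3 of 16 rose and 1 fell, with 0 in either direction adjusted over the list alone (median 0.87, camera adjusted p = 0.0435, adjusted p = 0.605 with an estimated correlation). Pdgfrb, a pericyte receptor gene, rose by 1.86 ± 0.52, and Tagln, a smooth muscle cytoskeletal gene, by 1.79 ± 0.57.

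The pericyte list was not past the threshold without any one of M580, M566, F578, M610, M605, M5, M602 or M2 (camera adjusted p from 0.0527 to 0.0861). Over 31 alternative settings it lost its call in 17 and reversed in 1, and median-ratio scaling gave a camera adjusted p of 0.0722. Without control M602, Pdgfrb had an adjusted p of 0.0582 and Tagln of 0.107, and Tagln had 0.0684 without M2. In the fat-titled anomalies alone Pdgfrb stood at 1.14 (adjusted p = 0.247) and Tagln at 0.61 (0.483).

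Cdh5, the gene whose promoter drives Cre (chromosome 8, 104101625 to 104144511), had 9.87 ± 0.97 log2 CPM in the anomalies and 8.60 ± 0.52 in the controls (SD, n = 7 and 4). Its log2 fold change of 1.27 ± 0.49 (SE) was not past the threshold (adjusted p = 0.0614). Without animal 18f its adjusted p was 0.0136, and without M566 it was 0.0266. With limma-voom it was 0.0141 and with library totals 0.0172. Without M580 it was 0.0931 and without F539 it was 0.119. Over 32 alternatives Cdh5 stayed short of the threshold in 24 and passed in 8, among them the looser threshold of 0.10. The count of genes past the threshold was 5817 without 18f and 3028 without control M602.

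The macrophage, T and NK cell, interferon and cytokine lists were higher by camera. In the macrophage list 12 of 20 members rose, and 16 adjusted over the list alone, with a median log2 fold change of 1.90 (camera adjusted p = 1.32e-06, adjusted p = 0.430 with an estimated correlation). Ms4a7 rose by 2.68 ± 0.43 and Fcgr1, the gene of a high-affinity antibody receptor, by 2.61 ± 0.46. In the T and NK cell list 6 of 14 rose, 6 also adjusted over the list alone (median 1.46, camera adjusted p = 0.000446, adjusted p = 0.430 with an estimated correlation). Cd4, the helper T cell coreceptor gene, rose by 2.68 ± 0.57, and Cd3d, of the T cell receptor complex, by 2.50 ± 0.65. In the interferon response list 15 of 20 rose, and 17 adjusted over the list alone (median 1.82, camera adjusted p = 1.52e-07, adjusted p = 0.430 with an estimated correlation). The antiviral genes Oasl2 and Oas1a, which have close paralogs, rose by 2.46 ± 0.42 and 2.39 ± 0.43. In the cytokine and chemokine list 10 of 20 rose, and 11 rose and 1 fell adjusted over the list alone (median 1.79, camera adjusted p = 0.000212, adjusted p = 0.384 with an estimated correlation). Il1rn, the interleukin 1 receptor antagonist gene, rose by 4.28 ± 0.71, and Tnf by 2.22 ± 0.42.

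The B and plasma cell and lymph node stroma lists were less firm. In the B and plasma cell list 2 of 12 members rose, and 0 adjusted over the list alone (median 1.72, camera adjusted p = 0.0127, adjusted p = 0.600 with an estimated correlation). Bank1, a B cell scaffold gene, rose by 1.40 ± 0.42, and Cd79b, of the B cell receptor, by 1.94 ± 0.67. In the lymph node stroma list 2 of 4 rose, and 3 adjusted over the list alone (median 2.41, camera adjusted p = 0.0313, adjusted p = 0.430 with an estimated correlation). Only these 4 of its 10 members passed the filter on low values. With a filter of at least 1 CPM in 4 animals the list was not past the threshold (median 1.72, camera adjusted p = 0.0648). Madcam1, an addressin gene, rose by 4.75 ± 1.20 (adjusted p = 0.0110), and by 5.53 without F539 and 5.57 without M610, and Cxcl13, a B cell chemokine gene, by 3.10 ± 1.05 (2.47 without M5). With limma-voom none of these genes was past the threshold, at adjusted p of 0.0574 for Madcam1, 0.157 for Cxcl13, 0.120 for Cd79b and 0.0523 for Bank1, nor were the B cell (0.0625) and lymph node (0.108) lists. In the fat-titled anomalies alone these lists had camera adjusted p of 0.240 and 0.275, and the B cell list had 0.187 with fry. The B cell list was not past the threshold without M580 (camera adjusted p = 0.0526), nor was the lymph node list without M580 (0.0548), M566 (0.0508) or M5 (0.0606). Bank1 was not past it without M602 (adjusted p = 0.0636) or M2 (0.0617). Cd79b was not past it without any one of M580, F578, M278, M605, F539, M5, M602 or M2 (adjusted p from 0.0507 to 0.110). Cxcl13 was not past it without M580 (0.0665), M566 (0.0514), F578 (0.0612), M5 (0.117) or M602 (0.0999). In the neutrophil list 1 of 6 members rose, 1 also adjusted over the list alone, and the list was not past the test (median 1.68, camera adjusted p = 0.0743). It was past it without F578 (0.0474) or F539 (0.0224), without the animals with f or F (0.0194) and with no filter (0.0495).

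Cell cycle genes rose in full. In that list 23 of 23 members rose, 23 also adjusted over the list alone, with a median of 2.47 (camera adjusted p = 1.77e-14, adjusted p = 0.430 with an estimated correlation). Rrm2, a ribonucleotide reductase gene of DNA synthesis, rose by 2.47 ± 0.30, and Mki67 by 2.94 ± 0.38. In the extracellular matrix list 9 of 28 rose, 9 also adjusted over the list alone (median 1.13, camera adjusted p = 0.000157, adjusted p = 0.461 with an estimated correlation). Timp1, a metalloproteinase inhibitor gene, rose by 4.42 ± 0.64, and Tgfb1, a fibrogenic cytokine gene, by 1.72 ± 0.34. In the immediate early list, whose genes also respond to tissue handling, 11 of 14 rose, and 13 adjusted over the list alone (median 1.65, camera adjusted p = 1.32e-06, adjusted p = 0.384 with an estimated correlation). Ier2 rose by 1.56 ± 0.21 and Junb by 2.38 ± 0.33.

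The platelet, erythroid and coagulation lists also passed camera, and the erythroid list differed between animals. In the platelet and megakaryocyte list 3 of 5 members rose, and 4 adjusted over the list alone (median 1.74, camera adjusted p = 0.0127, adjusted p = 0.424 with an estimated correlation). Gp1bb, of the von Willebrand factor receptor, rose by 2.44 ± 0.47, and Clec1b, a platelet receptor gene, by 2.48 ± 0.64. The highest Gp1bb value, 3.03 log2 CPM, was that of M580, and without M580 Gp1bb did not pass the filter and was not tested. This list was not past the threshold without M580 (camera adjusted p = 0.0794) or without M580 and M566 (0.0541). In the erythroid list 1 of 7 rose, 1 also adjusted over the list alone (median 1.98, camera adjusted p = 0.0148, adjusted p = 0.461 with an estimated correlation). That member was Slc25a37, a mitochondrial iron importer gene, at 1.17 ± 0.24, while the globin gene Hba-a2 stood at 2.05 ± 0.89 (adjusted p = 0.0882). The erythroid mean was 9.26 log2 CPM in M580, 9.22 in F578 and 7.78 in 18f, 5.53 and 7.17 in the pieces of M566, and 5.86 to 6.16 in M610, M278 and M605, against 4.64 to 6.18 in the controls. The list was not past the threshold without the animals with f or F (median 0.95, camera adjusted p = 0.113), without M580 and M566 (0.0529) or with fry (0.0850). In the coagulation and fibrinolysis list 5 of 18 rose and 1 fell, with the same counts adjusted over the list alone (median 1.15, camera adjusted p = 0.0127, adjusted p = 0.457 with an estimated correlation). F5, the coagulation factor V gene, rose by 2.25 ± 0.28, and Plau, the urokinase gene, by 1.87 ± 0.36. The coagulation list was not past the threshold without the animals with f or F (median 0.66, camera adjusted p = 0.0806) or in the subQ-titled anomalies alone (0.0504). With library totals 11 of its members rose and 0 fell, but the list was not past the threshold (camera adjusted p = 0.167).

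**Figure D2:**
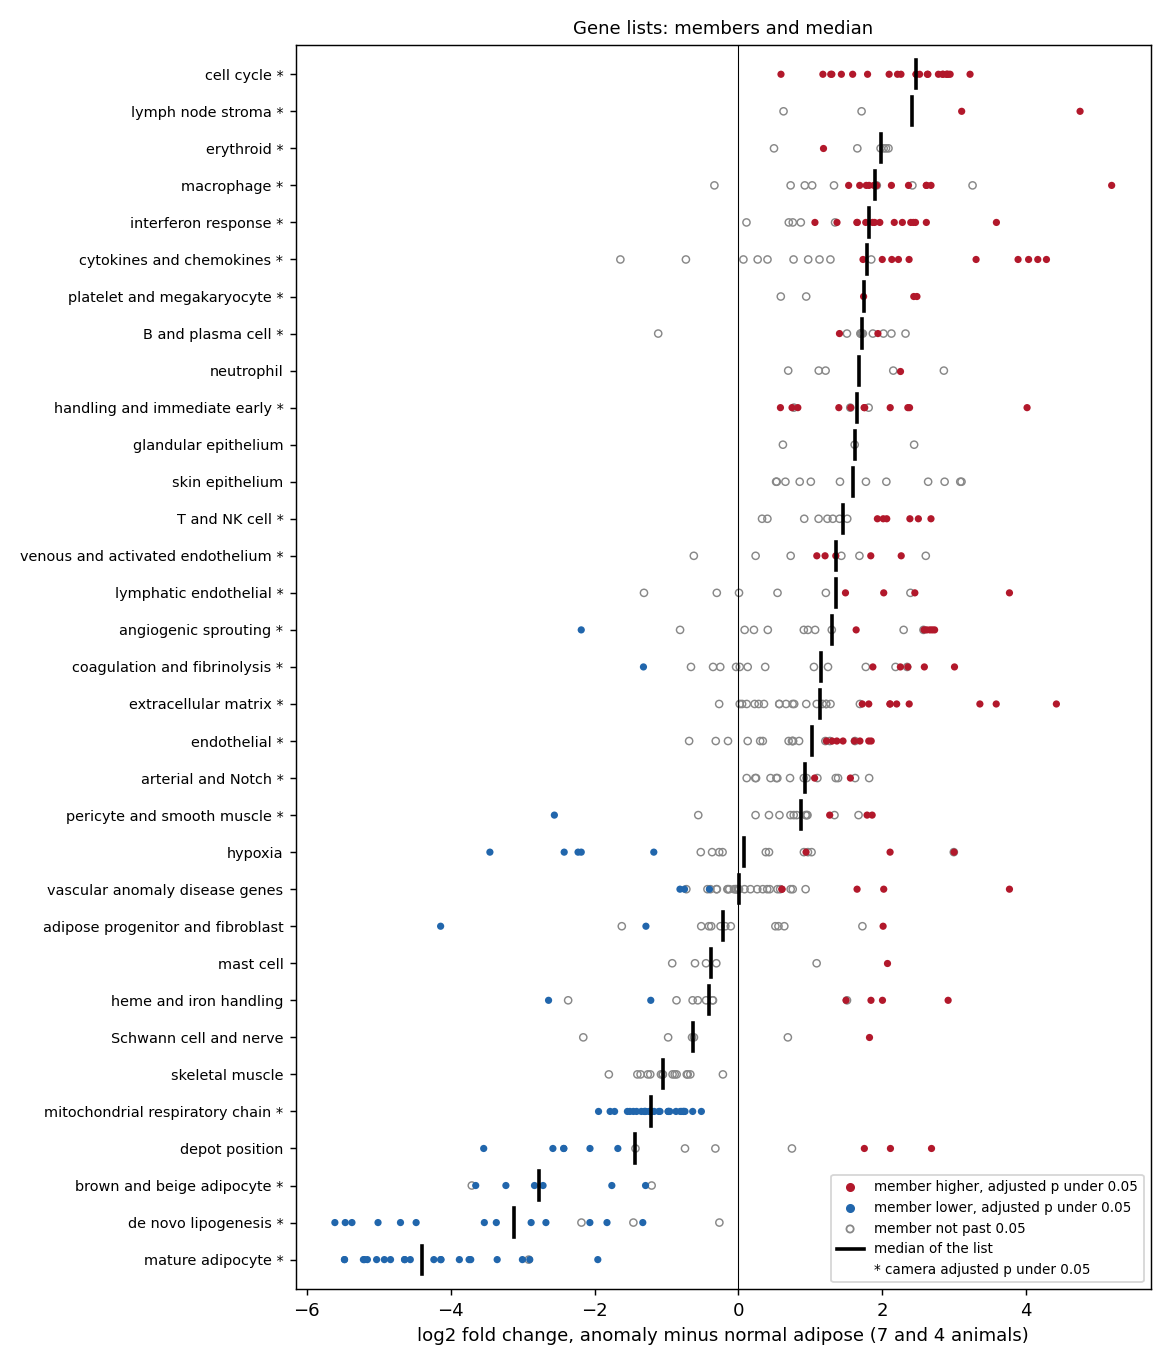
Log2 fold change, anomaly minus normal adipose (horizontal axis), of the members of each tested list (points, filled where past an adjusted p of 0.05) with the list median (bars) and a star where camera passed. The mature adipocyte list has a median of -4.40 and the cell cycle list of 2.47.

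Several lists held members that moved both ways. In the hypoxia list 3 of 18 members rose and 5 fell, with the same counts adjusted over the list alone (median 0.08, camera adjusted p = 0.833). Pfkfb3 and Hk2, both of glycolysis, changed by -3.46 ± 0.35 and -2.23 ± 0.35. In the heme and iron list 4 of 14 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.915, and 0.0390 in the fat-titled anomalies alone). Hmox1, the heme oxygenase 1 gene, rose by 2.91 ± 0.72, and Trf, the transferrin gene, changed by -2.64 ± 0.59. That list's median of -0.41 and its camera direction, up, differed in sign. In the fibroblast list 1 of 14 rose and 2 fell, with the same counts adjusted over the list alone (median -0.22, camera direction up, camera adjusted p = 0.976). Gsn, the gene of the actin-severing protein gelsolin, changed by -4.14 ± 0.72. The fibulin gene Fbln1 rose by 2.01 ± 0.55, was not past the threshold without M602 (adjusted p = 0.0622) or M2 (0.0570), and stood at 2.67 without F539 (0.00161). In the depot position list 3 of 13 rose and 6 fell, and 4 rose and 6 fell adjusted over the list alone (median -1.43, camera adjusted p = 0.579). The homeobox genes Hoxc8 and Hoxd8 changed by -3.54 ± 0.59 and 1.75 ± 0.26. In the list of genes mutated in vascular anomaly disorders 5 of 33 rose and 3 fell, with the same counts adjusted over the list alone (median 0.01, camera adjusted p = 0.187). Nras, a small GTPase gene, rose by 0.60 ± 0.12. With scaling by library totals 16 of that list rose and 0 fell, while the median of all genes moved up by 0.43.

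Markers of neighbouring tissues varied between animals. The skin epithelium list had a mean of 6.61 log2 CPM in control F539 and between 0.42 and 1.53 in the other controls, and 8.58 and 9.84 in the pieces of M566. In the anomalies M610 and M278 it was -0.05 and -0.28. None of its 12 members passed, over all genes or adjusted over the list alone (median 1.59, camera adjusted p = 0.148), and the list was past the test without M610 (0.0408), M278 (0.0442) or F539 (0.0194), and in the subQ-titled anomalies alone (0.0171). The glandular list, with 0 of 3 members past in either count, had a median of 1.62 (camera adjusted p = 0.531) and a mean of 7.90 log2 CPM in F539. The skeletal muscle list, with 0 of 15 past in either count, had a median of -1.05 (camera adjusted p = 0.443, and 0.0422 with no filter). The Schwann cell list had 1 of 6 members higher, 1 also adjusted over the list alone (median -0.63, camera direction up, camera adjusted p = 0.871). The mast cell list had 1 of 6 higher, and 0 adjusted over the list alone (median -0.38, camera direction up, camera adjusted p = 0.620). Of the 2 measured mesothelium genes 1 was higher, 1 also adjusted over the list alone. Control F539, whose skin and glandular means were highest of the controls, also had the highest lipogenesis mean, 10.97 against 8.09 to 8.90 log2 CPM in the others.

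**Figure D3:**
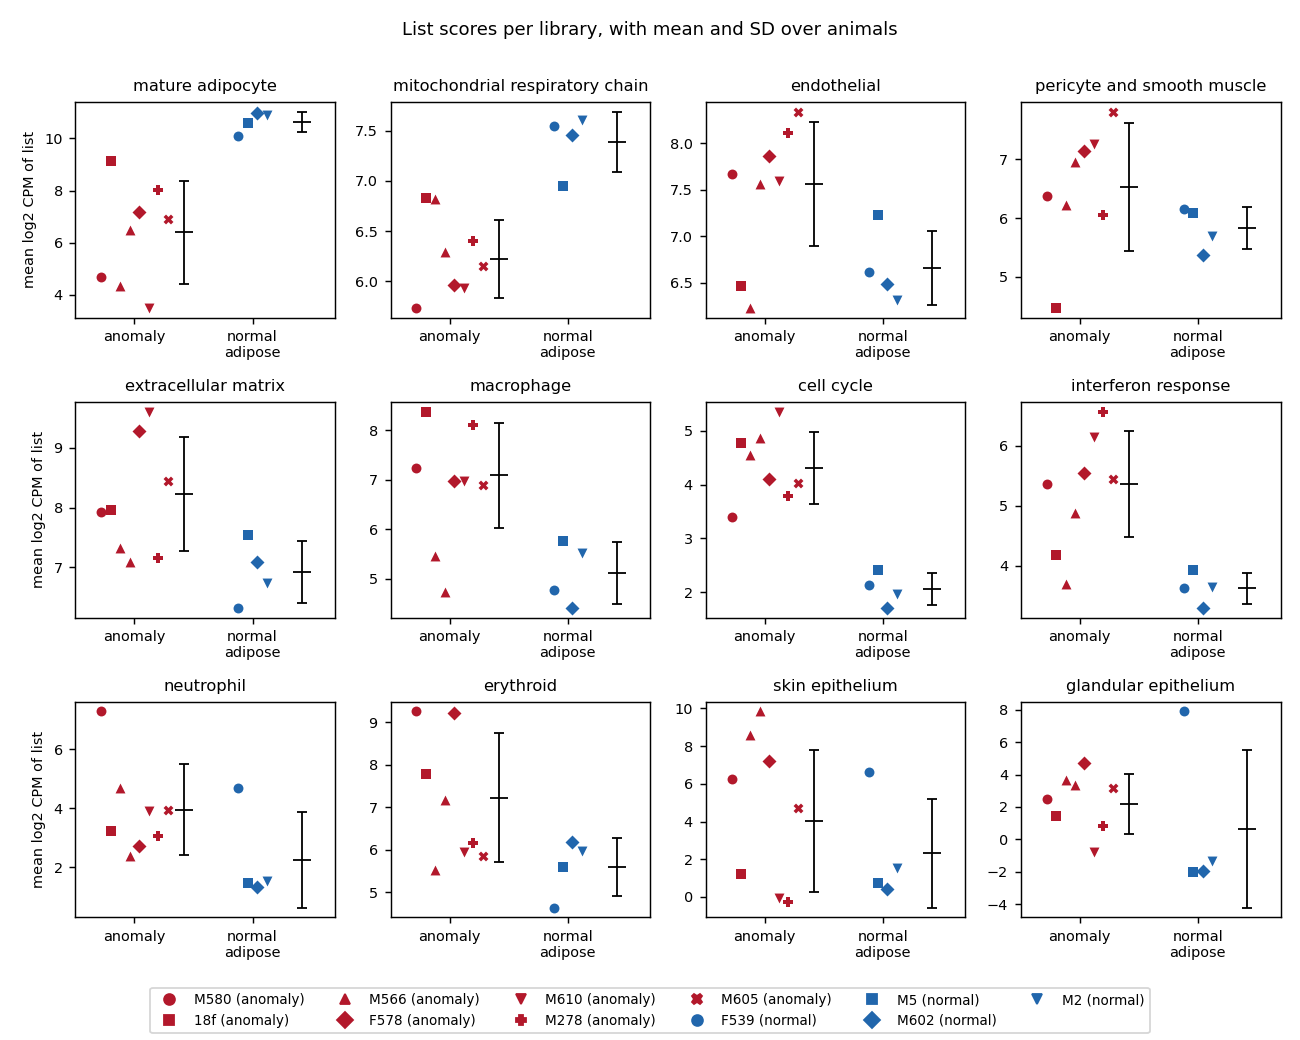
Mean log2 CPM over the members of 12 gene lists (vertical axes) in each library (points, 1 symbol per animal), with the mean and SD over animals (bars). The mature adipocyte mean lies between 10.11 and 10.96 in the controls and between 3.50 and 9.13 in the anomalies.

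By camera, 22 of 33 lists passed, 18 higher and 4 lower. Over all tested genes 1985 of 12955 were higher past the threshold. The counts of the arterial (2 of 16), erythroid (1 of 7) and disease gene (5 of 33) lists did not exceed that share. Those of the B cell (2 of 12) and pericyte (3 of 16) lists lay close to it. With an estimated correlation 0 passed, with 3 at an unadjusted p under 0.05, and with fry 15 passed. Of the tested genes 20.7% had no overlap between the groups, where chance gives 0.606%. The balance of calls depended on the scaling: 39.8% of the calls were higher as deposited and 74.5% with library totals (4618 higher, 1583 lower), which moved the median of all genes by 0.43. The list calls for B cell, sprouting, arterial, coagulation, erythroid, lymph node, lymphatic, pericyte, platelet and venous genes ended with library totals (camera adjusted p from 0.0837 to 0.525).

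Sex-linked genes were read per library. Xist, the gene of the RNA that silences an X chromosome in females, stood at 9.23 log2 CPM in 18f, 9.71 in F578 and 9.38 in F539. There the Y-linked gene Ddx3y had 12, 2 and 0 reads. In the other animals Ddx3y lay between 4.56 and 6.70 log2 CPM. In M566, Xist was 3.30 in the leg and 5.97 in the arm piece, while Ddx3y was 5.35 and 4.92. In the other animals with Ddx3y, Xist lay between -2.18 and 1.33. The cause of the higher Xist in M566 was not tested, and its pieces count as the same animal in all tests here.

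The second comparison set the anomalies titled subQ (5 animals) against those titled fat (2 animals), since the control titles all say fat and site and lesion are partly confounded. Adipocyte genes were lower in the subQ-titled anomalies, with a median log2 difference of -2.98 over the mature adipocyte list (camera adjusted p = 5.72e-11, adjusted p = 0.501 with an estimated correlation). Pericyte and smooth muscle genes were higher by 1.57 (camera adjusted p = 2.91e-09, adjusted p = 0.501 with an estimated correlation), and skin genes by 5.45 (camera adjusted p = 1.97e-07, adjusted p = 0.501 with an estimated correlation). Macrophage genes were lower, with a median of -1.30 (camera adjusted p = 1.52e-05, adjusted p = 0.553 with an estimated correlation). Against the controls, the adipocyte medians were -5.27 for subQ-titled and -2.19 for fat-titled anomalies, and the macrophage medians 1.42 and 2.84. By camera 16 of 33 lists passed, and with an estimated correlation 0 did, the lowest adjusted p being 0.501.

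Of single genes, 5 of 12955 passed in this second comparison, with 1921 at an unadjusted p under 0.05, and they are named after their values were seen. Prdx1 and Srxn1, both antioxidant enzyme genes, were lower in subQ-titled anomalies, at -1.68 ± 0.18 (adjusted p = 0.0372) and -1.80 ± 0.24 (adjusted p = 0.0397). Vwa3a was lower, at -3.53 ± 0.47. The translation factor gene Eif3j1, at 2.38 ± 0.30, and the collagen gene Col23a1, at 2.72 ± 0.35, were higher. The count was 0 without F578 (1783 at an unadjusted p under 0.05), 3 without M566 and 208 without M278, where the fat-titled arm is 1 animal assumed to vary like the others.

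The third comparison asked whether the leg and arm pieces of M566 lay closer to each other than pieces of different animals. Their deviations from the anomaly mean correlated at r = 0.275 across 12969 genes, above the 27 pairs from different animals, which lay between -0.587 and 0.250. With no low-value filter r was 0.165 and 3 of the 27 pairs were higher, up to 0.261, so this order depended on the filter. Genes are not independent replicates, and no test was made. The pieces differed more than 2-fold in 2352 genes, against a median of 2705 in the other pairs (1197 to 4031).

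The library of M580 differed from the others in its low values. It had 9367 genes at exactly 1 step above the floor, against 2630 to 3044 genes in the other libraries, and 1 step there was worth 0.742 CPM.

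**Figure D4:**
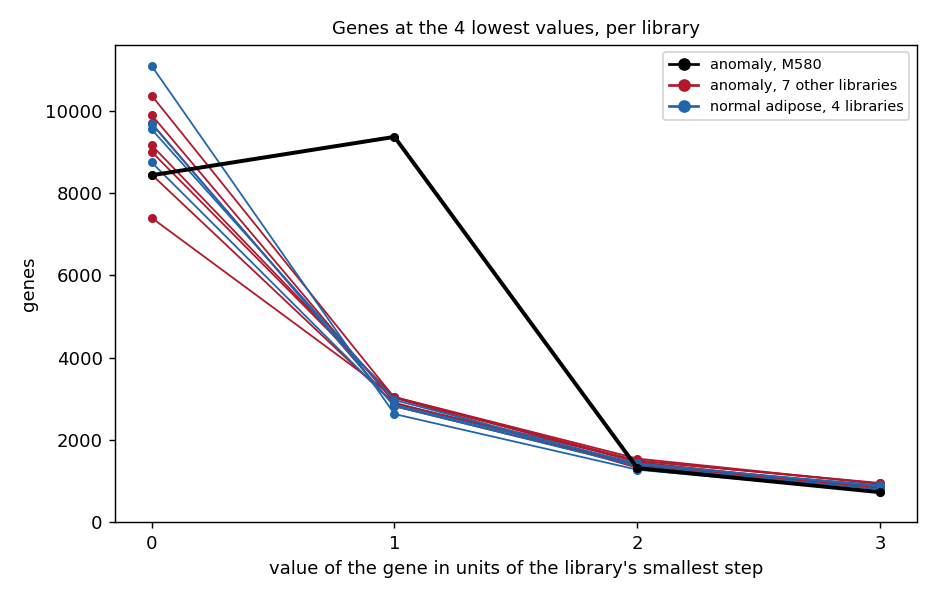
Number of genes (vertical axis) whose value was 0, 1, 2 or 3 of a library's smallest steps above the floor (horizontal axis), 1 line per library. The library of M580 has 9367 genes at 1 step, and the others between 2630 and 3044.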

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

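The tests of counting depth in the M580 library and of the adipocyte share were chosen only after their results were seen; the other tests here were set before.

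The library of M580 held 9367 genes at exactly 1 step above the floor. Counting at a depth of 953994 reads would give 2281 such genes, and the ratio of 4.11 argues against a shallow library counted like the others. Dividing each other library down to the same step and rounding up gave 6464 to 9929 such genes, a range that holds the observed 9367, so a deeper library that was scaled down and rounded up is a candidate explanation. Its true depth, and whether other libraries were treated so, stay open, and no biological explanation was tested. Without M580, 4644 genes passed.

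In the second pattern, adipocyte genes were lower while macrophage, cell cycle and interferon genes were higher. A lower share of adipocytes alone would raise the other cell types alike, yet the gap between the macrophage and fibroblast means differed by 2.22 on the log2 scale between the groups (exact permutation p = 0.0121, and 0.0242 adjusted over 10 gaps), and the gaps of endothelial, cell cycle, interferon, T and NK cell and matrix genes by 1.15, 2.50, 1.99, 1.80 and 1.55 (adjusted p from 0.0152 to 0.0404). The gaps of pericyte (0.95, adjusted p = 0.121), mast cell (0.39, 0.687), Schwann cell (-0.07, 0.897) and skeletal muscle genes (-0.77, 0.687) did not differ past the threshold. All 10 gaps share the fibroblast list as reference, and the test was chosen after its result was seen. The p-values therefore describe the gaps and are not an independent test of the adipocyte share. The cell cycle, interferon and matrix lists also do not each mark 1 cell type. A lower adipocyte share may still be part of the cause. For the site word in the titles, at the lowest 86.4% of the genes called in subQ-titled anomalies moved the same way in the fat-titled anomalies against other controls (at the lowest 72.3% in 18f alone), with smaller changes there, at a median ratio of 0.42 to 0.83 over the pairings. The site values argue against the site word as the whole cause, while the gaps do not decide how much the adipocyte share contributes. The title words cannot separate the lesion from the depot of the tissue, so a difference of depot stays open. A difference of the lesion itself, which the design names, stays open as a hypothesis, as does tissue handling.

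The third pattern is the number of genes changed. Of 100 of the 330 splits of the animals into 7 and 4, only the real one gave as many as 4986 genes. The splits not drawn were not examined, so this argues against chance without excluding it. The highest other split gave 3836. That split exchanged anomaly 18f with control F539, and both libraries have high Xist and few Ddx3y reads. In mature adipocyte genes 18f had the highest mean of the anomalies, 9.13 log2 CPM, and F539 the lowest of the controls, 10.11. The next highest split gave 32. Why that exchange gives so many genes was not tested, and the count without 18f was 5817 and without F539 it was 5122.

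Some animals lay apart from their group, in 11 of 204 sets of group values, where chance gives about 10.2. Control F539 had Ccn4 at 1.56 log2 CPM (others -2.09 to -1.90) and Pfkfb3 at 9.41 (others 10.66 to 10.90). Its list means were 4.67 for neutrophil genes (others 1.31 to 1.52), 6.32 for heme and iron genes (others 6.64 to 6.70) and 7.90 for glandular genes (others -2.03 to -1.34). Control M5 had Tgfb1 at 6.34 (others 5.50 to 5.55) and a fibroblast list mean of 6.68 (others 5.98 to 6.04). Control M2 had a platelet list mean of 1.90 (others 1.32 to 1.34). Among the anomalies, M566 had Fcgr1 at 3.34 (others 4.99 to 5.98), M610 had Madcam1 at -1.49 (others 3.08 to 5.38), and M580 had a neutrophil list mean of 7.29 (others 2.73 to 3.95).

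Differences between subQ-titled and fat-titled anomalies passed the test of the difference itself in 16 lists by camera and in 5 genes by limma. The median log2 differences, subQ minus fat, were 0.34 for endothelial, 0.98 for arterial and Notch, 1.18 for lymphatic, 0.76 for sprouting, 1.57 for pericyte, 0.77 for matrix, 1.49 for B and plasma cell and 0.28 for hypoxia genes. They were 1.62 for skeletal muscle, 5.45 for skin, 1.04 for Schwann cell and 0.52 for immediate early genes. They were -2.98 for mature adipocyte, -0.54 for respiratory chain, -1.30 for macrophage and -1.46 for heme and iron genes. With an estimated correlation 0 of these lists passed, the lowest adjusted p being 0.501. The genes were Eif3j1 (2.38), Col23a1 (2.72), Prdx1 (-1.68), Srxn1 (-1.80) and Vwa3a (-3.53), and without F578 the count was 0, without M566 3 and without M278 208.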

How the results depend on the processing

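The pseudocount of 1, the 1.5-fold test of limma and the run without M580 and M566 were chosen only after the data were seen. As deposited, 4986 genes passed (1985 higher, 3001 lower) and 22 lists. With library totals 4618 were higher and 1583 lower, 90 of the 4986 changed sign, and 13 lists passed. Adjusted p 0.01 gave 2502 (955 higher, 1547 lower), the 1.5-fold test of limma 1390 (582, 808), and the fat-titled anomalies alone, with fewer animals, 1518 (822, 696). Leaving out 1 animal gave 3028 (without control M602) to 5817 (without 18f) genes, 1205 to 2295 higher and 1823 to 3522 lower. With an estimated correlation 0 lists passed, with 3 at an unadjusted p under 0.05. In the fat-titled anomalies alone the pericyte median reversed to -0.45 (camera adjusted p = 0.462, over a range of 0.000606 to 0.605). Median-ratio (5327) and upper quartile (5284) scaling, limma-voom (5012), no filter (4925), the pseudocounts (4976 to 4984) and the run without M580 and M566 (4602) lay within 1.5 times. The site comparison gave 5 genes, 49 with no filter, and 0 (without F578) to 208 (without M278) with 1 animal left out, and 3 without M566. Causes were not tested. The M566 correlation of 0.275 was 0.270 and 0.281 with other priors, above the other pairs, and 0.165 with no low-value filter, where 3 of 27 other pairs were higher (the cause was not tested). Mature adipocyte, lipogenesis, brown adipocyte, respiratory chain, cell cycle, macrophage, T and NK cell, cytokine, interferon and immediate early calls ended with an estimated correlation and in no other setting run, and endothelial and matrix calls also with fry. Of the named genes, the fat-titled anomalies alone ended 23 calls, the 1.5-fold test 14, adjusted p 0.01 11, limma-voom 6 and the run without M580 and M566 3; none of the named genes that passed changed direction in any setting run. Over the lists, library totals ended 10 calls, fry 7, the run without M580 and M566 6, and the fat-titled anomalies 6, the reversed pericyte list among them. Cdh5 had adjusted p from 0.0136 to 0.412. Depth limits low genes most in M580, where 3 steps are 2.23 CPM. The model with correlated pieces of M566 had 1 pair and could not be fitted; the planned count tools were not run, since the values are log2. No paired analysis was possible because the replicate numbers name different animals in the groups.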

Other observations

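The 22 families in this part were chosen, and the membership of 6 of them was then narrowed, only after the data were seen. By camera 11 of the 22 passed, and with an estimated correlation 0 did, the lowest adjusted p being 0.398. Of 20 genes named for a C-type lectin domain 14 rose and 1 fell, with a median of 1.64, and Clec4n rose by 3.43. Of 6 Fc receptor genes 5 rose, among them Fcgr4 by 3.57, and of 25 integrin subunit genes 11 rose and 1 fell, with Itga5 at 2.31. Of 38 mitochondrial solute carriers 22 fell and 4 rose, and Slc25a10 changed by -3.13; with library totals 14 fell and 5 rose, and the median went from -0.69 to -0.26. Of 71 cytosolic ribosomal protein genes, whose near-identical copies make their values uncertain, 47 rose and 1 fell (median 0.66), and with library totals 65 rose and 1 fell. Of 76 mitochondrial ribosomal protein genes 42 fell and 1 rose (median -0.55), but with library totals 11 fell and 2 rose (median -0.12), a shift no different from the 0.43 by which library totals moved all tested genes. Of 26 semaphorin and plexin genes 9 rose and 1 fell (median 0.72, camera adjusted p = 0.00903), of 35 kinesin genes 14 rose and 7 fell (median 0.43, 0.0194), and of 12 matrix metalloproteinase genes 3 rose and 1 fell (median 0.93, 0.0440). Families that did not pass camera included these: of 37 proteasome subunit genes 1 rose and 2 fell (camera adjusted p = 0.415), of 20 cytochrome P450 genes 3 rose and 6 fell (0.724), and of 10 S100 genes 1 rose and 1 fell (0.394). Of 9 MHC class II genes 1 rose (0.0565). The same shift of all genes turned the signs of the proteasome and cytochrome P450 medians, from -0.13 to 0.29 and from -0.28 to 0.15. With library totals 9 proteasome genes rose and 0 fell, and 5 cytochrome P450 genes rose and 3 fell.

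The homeobox clusters were counted separately, and no test compared them with each other. With an estimated correlation none of them passed camera (adjusted p from 0.398 to 0.621). Of 4 measured HoxD genes 4 rose, with Hoxd10 at 4.47 and Hoxd9 at 2.68, and of 6 HoxC genes 5 fell, with Hoxc8 at -3.54 and Hoxc5 at -2.62, and the same counts passed with library totals. Of 5 HoxA genes 2 fell and of 7 HoxB genes 0 passed, while with library totals 3 HoxB genes rose. In the fat-titled anomalies alone, against the fat-titled controls, Hoxc8 stood at -2.59 and kept its call, and Hoxd8 stood at 1.58 and was not past the threshold (adjusted p = 0.0600). The depot position list was not past the threshold between subQ-titled and fat-titled anomalies (camera adjusted p = 0.0623).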
